A study of Homo sapiens with 6 samples.

How the data were processed

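Total RNA from 6 samples of Flp-In T-REx 293 cells, 3 clones under TET siRNA and the same 3 clones under non-targeting siRNA, was labelled with biotin and hybridised to one-colour Affymetrix arrays, per the labels. The values are intensities on a linear scale, MAS5 signals per probe set, deposited by the authors as 1 column per array. MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited intensities had already been scaled: the mean without the highest and lowest 2% of probe sets was 1000 on each array, so no further normalization was applied. MAS5 summarises each probe set from perfect-match and mismatch probes array by array, which leaves dim probe sets noisy and lets a scaling difference between arrays pass into every value. Detection calls and scanner files were not used here, and the order and batch of hybridisation are not given in the sources used here.

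Of 54675 probe sets, 62 controls were set aside, leaving 54613. Platform annotation gave 1 gene for 41091 of these, several for 1801 and none for 11721; only probe sets with 1 gene were named. Of the 41091, 41037 were found by Entrez ID in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. Signals were taken to log2, and the upper 50% of probe sets by mean log2 signal over all 6 arrays were tested, which is a geometric mean signal of at least 117. This left 27306 probe sets, 23156 of them with 1 gene, for 12318 genes; 2471 carried the suffix of probe sets that can cross-hybridise.

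The knockdown was compared with the control in limma 3.58.1 (R 4.3.3) with a trended, robust empirical Bayes step and no clone term, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Errors given as SE come from that fit and errors given as ± are SDs over 3 arrays. The TET probe sets were read from the same fit without the brightness filter and adjusted both over the 8 TET probe sets and over all. The 29 gene lists, which name 690 genes of which 512 were measured, were tested with camera at a preset inter-gene correlation of 0.01 against all genes with a tested probe set, using the brightest probe set of each gene; camera with an estimated correlation and fry were alternatives. Single values such as quality ratios and list means were compared with two-sided exact permutation tests, whose smallest p is 0.1 with 3 arrays per group. These tests shuffle all 6 arrays and ignore the clone pairs. Shuffling within the pairs would leave fewer arrangements and a larger smallest p. In the permutation tests the 6 quality measures had adjusted p-values of 0.8. The plots were drawn with matplotlib 3.10.9.

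The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule names TET1, TET2 and TET3 and, as fewer than 10 genes passed, every passing gene and the 10 genes of smallest p in each direction, with each gene ranked by its brightest probe set, so that a smaller p at a dimmer probe set does not count; in each list it names up to 4 passing members or else the 2 of smallest p. Alternatives covered the clone as a block, the brightness filter (none, or the upper 30%), a pseudocount of 36.1 (the 25th percentile of all signals), quantile normalization, plain empirical Bayes, each array and each clone left out, a plain t-test, other thresholds and the mean of all probe sets of a gene.

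The replicate number pairs arrays across the groups, because the labels give it as the number of the clone. The deviations of same-clone arrays from their group means correlated across probe sets at 0.493, 0.234 and 0.236 for clones 1, 2 and 3, all above the limit of 0.1 fixed for this check. Among arrays of different clones the highest value was 0.219, between knockdown replicate 2 and control replicate 3, nearly as high as for clones 2 and 3, so clone 1 alone stands clearly apart. The first principal component (39.7% of the variance) separated both arrays of clone 1 from the rest. The median residual SD was 0.20 without and 0.13 with the clone as a replicate block. The steps were tested on a single draw of simulated data, with 200 of 27306 probe sets changed. Its clone means and spreads were those of the fit with the block. The fit without the clone recovered 1% of changes of 0.5 on the log2 scale and 32% of changes of 1, with 0 false calls among 33. The fit with the block recovered 48% and 75%, with 14 false calls among 137. Clone differences were thus built into the simulated arrays, which favours the block, so these shares do not decide between the fits. A shift of -0.3 simulated for the mitosis list was recovered in both fits, with 0 of the 28 other lists called. The noise was drawn independently for each probe set. The simulation therefore tests neither smaller list shifts nor false list calls among correlated genes.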

Results

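The data were 6 one-colour Affymetrix arrays of total RNA from Flp-In T-REx 293 cells, a derivative of the human embryonic kidney line HEK293 made for placing a transgene at a fixed genomic site. The cells carried an inducible GFP transgene that was left uninduced. In one group of 3 arrays, siRNAs against TET1, TET2 and TET3 had been given together, and in the other group of 3 arrays a pool of non-targeting siRNAs, with RNA taken 96 h later in both. The labels name the same 3 clones in each group, so every clone had a knockdown array and a control array. TET1, TET2 and TET3 are the dioxygenases that oxidise 5-methylcytosine in DNA, and the comparison asks how the transcriptome of these cells changes when all 3 are depleted at once. The trimmed mean signal was 1000 on every array, and the number of arrays limits the precision of every value given here. Pearson correlations of log2 signal between arrays were 0.972 to 0.986.

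All 3 targeted transcripts were lower in the knockdown, TET1 most of all. The brighter TET1 probe set (Entrez gene 80312) gave a signal of 585 ± 123 in the knockdown and 3222 ± 216 in the control (SD, n = 3 each), which left 17.9% of the control level (95% interval 13.8 to 23.2%) and 14.6, 19.9 and 19.7% in clones 1, 2 and 3. The dimmer TET1 probe set, of the type that can cross-hybridise, left 22.1%. The brightest TET3 probe set (Entrez gene 200424) had a signal of 545 ± 44.8 against 1276 ± 160, or 42.9% of control (34.2 to 53.8%), and that of TET2 (Entrez gene 54790) had 380 ± 85.5 against 801 ± 78.6, or 46.8% (34.3 to 63.8%). The log2 differences in limma were -2.48 (SE 0.17) for TET1, -1.10 (SE 0.20) for TET2 and -1.22 (SE 0.15) for TET3, each negative in 3 of 3 clones. Adjusted over the list alone, that is over the 8 TET probe sets, the limma adjusted p was 4.83e-07 for TET1, 0.00069 for TET2 and 3.43e-05 for TET3. Adjusted over all probe sets without the filter on dim ones, TET1 passed (limma adjusted p = 0.0033), while TET2 (0.327) and TET3 (0.1003) did not. With the clone as a replicate block both passed (TET2 0.0335, TET3 0.0196).

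The other 4 TET probe sets were dim and lay below the filter. One of TET2 differed by -2.82 on the log2 scale with 14.2% of control left, and its 3 clones ranged from 1.87 to 61.9%. The remaining TET3 probe sets differed by -0.82 and -0.55. The last TET2 probe set differed by 0.23, was higher in clone 2 alone and went against the other TET2 probe sets, at a mean control signal of 53.7 ± 41.3 (SD, n = 3).

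**Figure D1:**
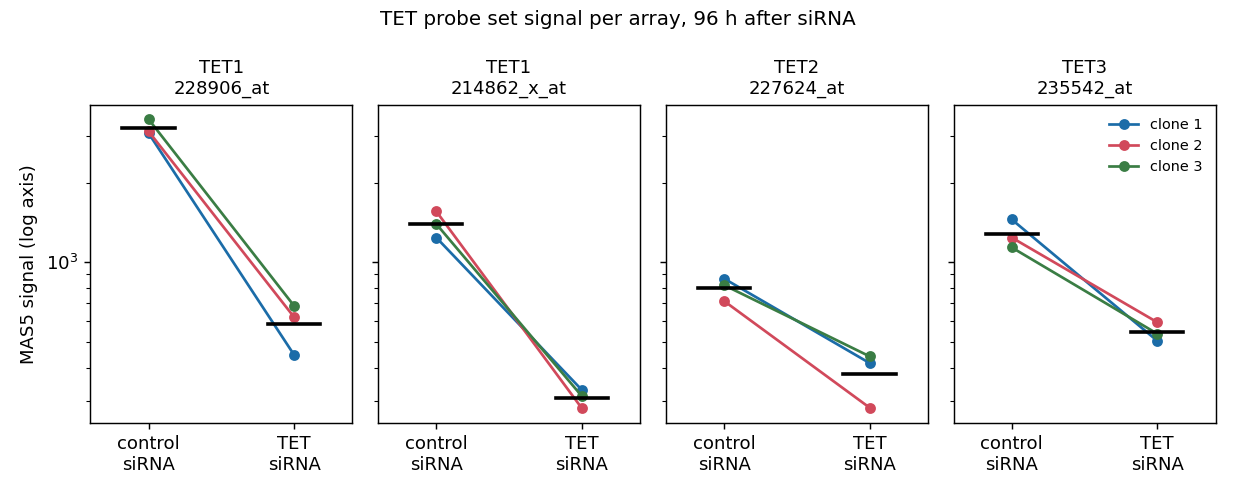
MAS5 signal on a log axis for the 4 TET probe sets above the brightness filter, by siRNA treatment; each line joins the control and knockdown arrays of a clone, and the short bar is the group mean (n = 3). Every clone lies lower in the knockdown for all 4 probe sets, with mean TET1 signal going from 3222 to 585 at its brighter probe set.

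In the fit without the clone, the only named gene besides TET1 to pass over all tested probe sets was CCNB2 (Entrez gene 9133), which was lower in the knockdown. It encodes cyclin B2, a partner of CDK1 at entry into mitosis. Its signal was 8080 ± 260 in the knockdown and 14375 ± 321 in the control (SD, n = 3 each), a 1.78-fold lower level (log2 -0.83, SE 0.07, limma adjusted p = 0.0095) seen in 3 of 3 clones, and the call held with the replicate block (adjusted p = 0.00055). A probe set without a gene name here, whose identifier stands in the plot of change per clone, fell by 0.82 on the log2 scale, from 4812 ± 183 to 2721 ± 68.2 (limma adjusted p = 0.0338). With the 2 TET1 probe sets these made 4 of 27306 tested probe sets past an adjusted p of 0.05, all lower, which stood for 2 named genes. At an unadjusted p under 0.05 there were 1805 (1012 higher, 793 lower). By chance alone a share of 0.05 of the 27306 would have such a p, so most of the 1805 could arise that way. The count past the adjusted threshold was 4 without knockdown replicate 1, 3 without control replicate 1, 2 without knockdown replicate 2 or 3 or control replicate 2 or 3, and 121 without replicate 1 of both groups. It was 0 in limma without replicate 2 or replicate 3 of both groups (946 and 550 at an unadjusted p under 0.05, both below that chance share). The CCNB2 call held without knockdown replicate 1, control replicate 1 or replicate 1 of both groups, but not without arrays of the other clones. Its limma adjusted p was 0.0814 without knockdown replicate 2, 0.198 without knockdown replicate 3, 0.133 without control replicate 2, 0.148 without control replicate 3 and 0.997 or more without replicate 2 or replicate 3 of both groups, while its log2 difference stayed between -0.86 and -0.79 in all of these. Without the trend and robust steps the adjusted p was 0.317 for CCNB2 and for the unnamed probe set, which also missed the threshold with no filter on dim probe sets (0.0652) and with any of the 6 arrays left out (0.0680 to 0.433).

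With the clone as a replicate block, the same comparison gave 282 probe sets past an adjusted p of 0.05 in limma, 105 higher and 177 lower, in place of 4. They stood for 212 genes, 83 higher and 129 lower. All 282 had the same sign in the 3 clones, which is close to a condition of being called in this fit. Most differences were small: the median size was 0.54 on the log2 scale, and 13 genes differed over 2-fold, the siRNA targets TET1, TET2 and TET3 among them. Leaving out TET probe sets, 278 of the 282 remain. This count depended on the model and the clones, since it was 0 when the variance trend and the robust step were left out of limma's moderation (3355 at an unadjusted p under 0.05), 70 with no filter on dim probe sets, 108 without clone 1, 684 without clone 2 and 63 without clone 3. In a single draw of simulated arrays the blocked fit made 14 false calls among 137, more than the nominal share.

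Ranked by the brightest probe set of each gene, the 10 genes with the smallest p among those higher in the knockdown did not pass in the fit without the clone (limma adjusted p 0.111 to 0.281), and all 10 passed with the replicate block (0.0037 to 0.0257), with 3 of 3 clones higher. Their levels were 1.31 to 1.87-fold above control. SELENOP, a secreted selenium transport protein, had a signal of 678 ± 120 against 359 ± 22.3 (SD, n = 3 each; log2 0.90, SE 0.17). APOC1, an apolipoprotein, differed by 0.84 and 1.06 at its 2 probe sets, both of a type that can cross-hybridise. SESN1 and SESN3, which encode sestrins, stress-inducible inhibitors of mTORC1 signalling, differed by 0.43 (SE 0.09) and 0.45 (SE 0.09). NAPEPLD, a phospholipase that makes N-acylethanolamines, differed by 0.73, and its other 4 tested probe sets had values of 0.34 to 0.88. ROBO1, a receptor for SLIT guidance proteins, differed by 0.54, the carbonic anhydrase CA13 by 0.62, the sorting nexin SNX12 by 0.63 and RGS2, a regulator of G-protein signalling, by 0.49. AMMECR1 differed by 0.39 and 0.42 at its 2 brighter probe sets, both past the threshold with the replicate block, and by -0.55 and 0.50 at its 2 dimmer ones.

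In the same ranking, the 10 genes with the smallest p among those lower in the knockdown and not passing without the clone held TET3 and 9 others, which lay 1.56 to 2.00-fold below control (limma adjusted p 0.0678 to 0.0729, and 0.0012 to 0.0028 with the replicate block) with 3 of 3 clones lower. LHFPL6 had a signal of 1436 ± 219 against 2852 ± 119 (SD, n = 3 each; SE of the log2 difference 0.13). MTMR9, a myotubularin-related protein, differed by -0.98 at its brightest probe set, by -0.64 at the next (adjusted p with the replicate block 0.0253) and by 0.08 at the dimmest. PXYLP1, a phosphatase acting in the synthesis of the glycosaminoglycan linker, differed by -0.97 and REXO4, of the RNA exonuclease family, by -0.79. RPN2, a subunit of the oligosaccharyltransferase of the endoplasmic reticulum, differed by -0.64, -0.61 and -0.72 at its 3 probe sets. The probe sets with -0.64 and -0.61 are of the type that can cross-hybridise. For several of these genes a second probe set did not show the difference: CCDC25 had -0.73 at the brighter and -0.03 at the dimmer of its probe sets, and the ubiquitin ligase UBE3C had -0.68 and -0.04 in the same order. EFCAB14 had -0.64 at its brightest probe set and -0.13 to -0.24 at the other 4. C1orf122 differed by -0.67 at its only tested probe set.

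**Figure D2:**
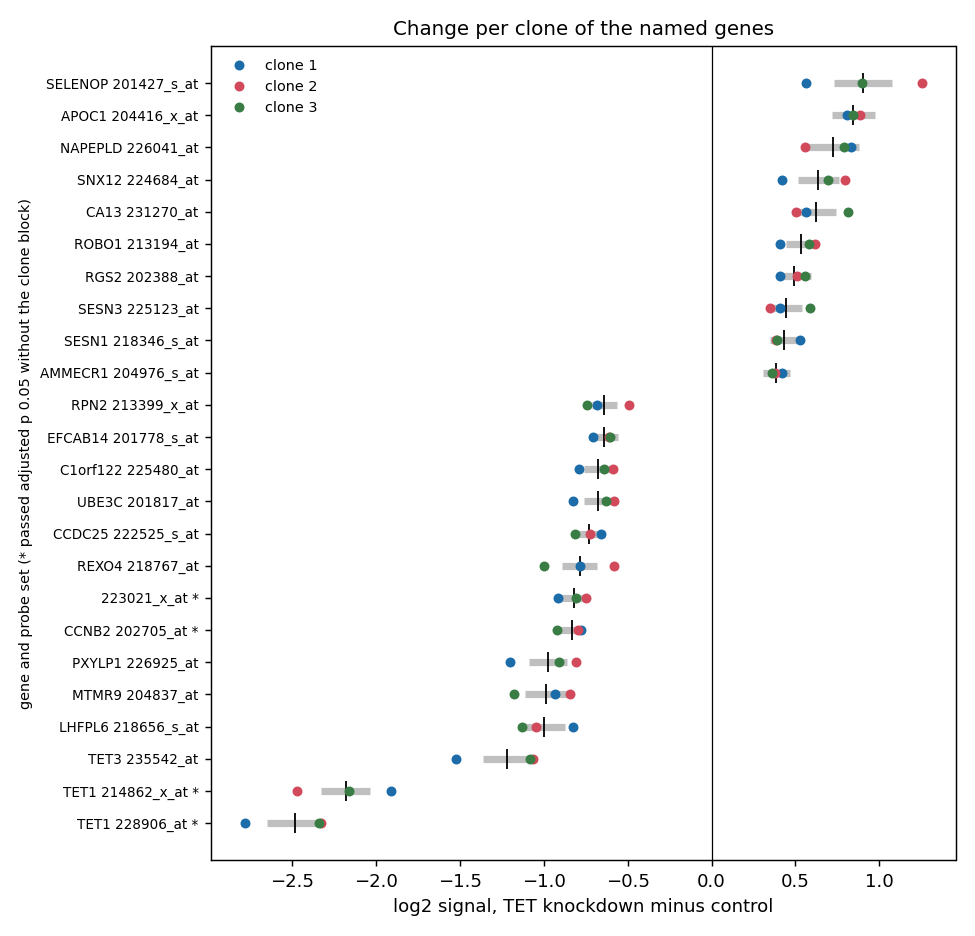
Log2 signal in the knockdown minus control for the named genes, with points for the 3 clones, a tick at the mean and a grey bar of 1 SE on each side from the fit without the clone; an asterisk marks probe sets that passed in that fit. The points of every gene lie on 1 side of 0, from -2.48 for TET1 to 0.90 for SELENOP in the mean. Choosing genes by small p favours such agreement between clones.

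Mitotic genes shifted down as a group. Of 31 measured genes of the mitosis list, 25 had a negative difference, the median was -0.10 on the log2 scale, and camera with its preset correlation placed the list below the other genes (adjusted p = 3.7e-06). Camera's adjusted p was 0.0607 with an estimated correlation, so the call did not hold there. With the replicate block it was 3.54e-05 with the preset and 0.484 with the estimated correlation. The estimates were -0.021 without and -0.006 with the block, below the preset of 0.01, so correlation between members does not explain the lost call. With an estimated correlation, camera also takes its degrees of freedom from the few arrays and not from the genes, which raises p. Fry gave the list an adjusted p of 0.0014 without and 0.0642 with the block. CCNB2 was the only member to pass in the fit without the clone, both over all probe sets and adjusted over the list alone. With the block 3 members passed over all (CCNB2, NUSAP1 and CENPF) and 5 adjusted over the list alone. NUSAP1, a spindle microtubule protein, differed by -0.42 and CENPF, a kinetochore protein, by -0.33 (adjusted p with the replicate block 0.0168 and 0.0475). The mean log2 signal of the list was lower by 0.15, 0.15 and 0.12 in clones 1, 2 and 3. The exact permutation p, two-sided and ignoring the clone pairs, was 0.1, the smallest this test allows with 3 arrays in each group. DNA replication genes gave a median of 0.0028 over 37 genes (camera adjusted p = 0.800), with RPA1 at 0.19 and RFC5 at 0.18, and the mean difference of mitosis minus replication was -0.15 (exact p = 0.1).

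Targets of p53 lay slightly higher, but over all 6 arrays the list passed with the clone in the fit and not without it. Of 23 measured genes 16 had a positive difference and the median was 0.10. Camera's adjusted p was 0.0997 without the clone and 0.0418 with the replicate block, and in the same order the adjusted p was 0.456 and 0.911 with an estimated correlation. In that order the estimates were -0.012 and 0.016, near the preset of 0.01. Without replicate 2 of both groups the list passed in the fit without the clone too (adjusted p = 0.0442). SESN1 (0.43) and TP53INP1 (0.62), a p53-induced protein that takes part in autophagy, passed adjusted over the list alone without the clone and over all probe sets with it. The TET list itself, whose 3 genes were the targets, gave a median of -1.22 (camera adjusted p = 3e-10, and 0.0607 with an estimated correlation of -0.105). Over all 6 arrays no other list of the 29 fixed in advance passed with camera, and no list passed with an estimated correlation. As even the silenced TET genes missed the threshold there, a miss with an estimated correlation says little about a list.

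For genes around DNA methylation, no list was called by camera. DNA methyltransferases and methyl-CpG readers had a median of 0.07 over 13 genes, 9 of them positive (camera adjusted p = 0.354), with ZBTB4 at 0.41, which passed adjusted over the list alone, and ZBTB38 at 0.39. With the replicate block, fry, which asks whether the members move on balance in 1 direction, called this list as higher (adjusted p = 0.0381) and no other. The call was not shared by fry without the block (0.119) or by camera with the block (0.643, and 0.911 with an estimated correlation). With the block, 2 members passed as higher and 2 as lower adjusted over the list alone. The median was -0.05 over 15 base excision repair genes (GADD45B -0.32, UNG 0.10; adjusted p = 0.800), 0.04 over 12 TET partners and 2-oxoglutarate enzymes, 10 of them positive (IDH3A -0.16, HCFC1 0.24; 0.800), -0.04 over 15 histone demethylases of the same cofactor (KDM7A -0.61, PHF8 -0.44; 0.800) and 0.04 over 15 Polycomb proteins (EZH1 -0.17, PHC2 -0.20; 0.827). KDM7A passed with the replicate block (adjusted p = 0.0191). Genes often silenced by DNA methylation showed no call: 12 imprinted genes had a median of -0.03 (PHLDA2 -0.28, SLC67A1 -0.36; 0.800), and only 3 of 25 germline genes were bright enough to test (median 0.13, PRAME 0.36, TEX14 -0.58; 0.827).

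Developmental and signalling lists gave no call over all 6 arrays either. HOX genes had a median of 0.08 with 18 of 25 positive (HOXB5 0.45, HOXD9 0.55; camera adjusted p = 0.317), and the list passed (0.0346) when control replicate 3 was left out. That call is at the preset correlation; over all 6 arrays the estimated correlation was 0.084, with an unadjusted p of 0.265, and the estimate was not tried with arrays left out. The median was -0.01 over 35 developmental transcription factors (ZIC2 0.15, LHX9 0.37), 0.05 over 22 Wnt genes (LGR5 0.26, TCF7L2 0.19), 0.01 over 21 TGF-beta, BMP and Nodal genes, 0.07 over 29 matrix and adhesion genes (ITGAV -0.36, LAMA4 0.40) and -0.05 over 13 epithelial and mesenchymal markers (KRT19 -0.22, ZEB1 -0.17), all with a camera adjusted p of 0.800. In the TGF-beta list, ID4, an inhibitor of bHLH factors, differed by -0.41 and passed adjusted over the list alone, and both ID4 and the receptor BMPR2 (0.43) passed with the replicate block. Camera's direction was down for the TGF-beta and Polycomb lists although their medians were above 0.

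Of the stress, metabolic and housekeeping lists, none was called by camera over all 6 arrays. The unfolded protein and amino acid stress list had a median of -0.04 over 25 genes (adjusted p = 0.571), with EDEM1, a factor of protein degradation at the endoplasmic reticulum, at -0.63 and TRIB3, a target of ATF4, at -0.60. Both passed adjusted over the list alone and with the replicate block. Heat shock genes had -0.01 over 12 genes (HSPA4 -0.31, which passed adjusted over the list alone, and BAG3 -0.14; 0.800), cholesterol synthesis -0.05 over 17 (TM7SF2 0.51, INSIG1 -0.19; 0.604), glycolysis and hypoxia -0.01 over 27 (PGK1 -0.26, VEGFA -0.26; 0.800) and oxidative phosphorylation -0.02 over 30 (NDUFS1 -0.19, COX7C 0.09; 0.800). Cytosolic ribosomal proteins had a median of -0.03 over 35 genes (RPS16 -0.09, RPLP1 -0.08; 0.800) and differed between clones, with medians of -0.21, 0.15 and -0.05 in clones 1, 2 and 3. The list passed as higher without knockdown replicate 1 (0.086, camera adjusted p = 4.85e-06) or replicate 1 of both groups (0.053, 0.0066), and as lower without knockdown replicate 2 (-0.12, 0.00025) or replicate 2 of both groups (-0.12, 0.00026). It also passed with the replicate block without replicate 2, which made 5 of 30 alternatives. These calls rest on camera's preset correlation of 0.01, while the correlation estimated between the ribosomal genes over all 6 arrays was 0.894 (0.883 with the replicate block), at which the list had an unadjusted p of 0.827. The estimate was not tried with arrays left out. Interferon genes had a median of 0.12 over 14 genes (IFIT5 0.25, HERC5 -0.14) and RNA interference factors 0.03 over 12 (TNRC6B 0.44, TNRC6C -0.25), both with a camera adjusted p of 0.800. Both groups had received siRNA, so a response to siRNA shared by them would not show here.

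Many cell type markers were dim or had no probe set. Those tested were 10 of 20 neuronal, 7 of 18 kidney epithelial, 5 of 12 fibroblast and 3 of 14 blood cell markers. Neuronal markers had a median of 0.07 over 10 genes (NEFL -0.19, CHGA 0.43; camera adjusted p = 0.800), kidney epithelial markers 0.0016 over 7 (LRP2 0.29, KRT7 -0.34; 0.953), fibroblast markers 0.26 over 5 (PDGFRA 0.82, COL1A1 -0.23; 0.800) and blood cell markers -0.13 over 3 (CD79A -0.13, ITGAM -0.14; 0.800). The mean was below 0 for the kidney and germline lists although their medians were above it. As a measure of RNA quality, the ratio of the 3′ to the 5′ control probe set was 2.00 ± 0.13 in the knockdown and 2.05 ± 0.03 in the control for ACTB (SD, n = 3 each; exact permutation p = 0.6) and 1.06 in both for GAPDH (exact p = 0.8), where 0.1 is the smallest p possible.

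**Figure D3:**
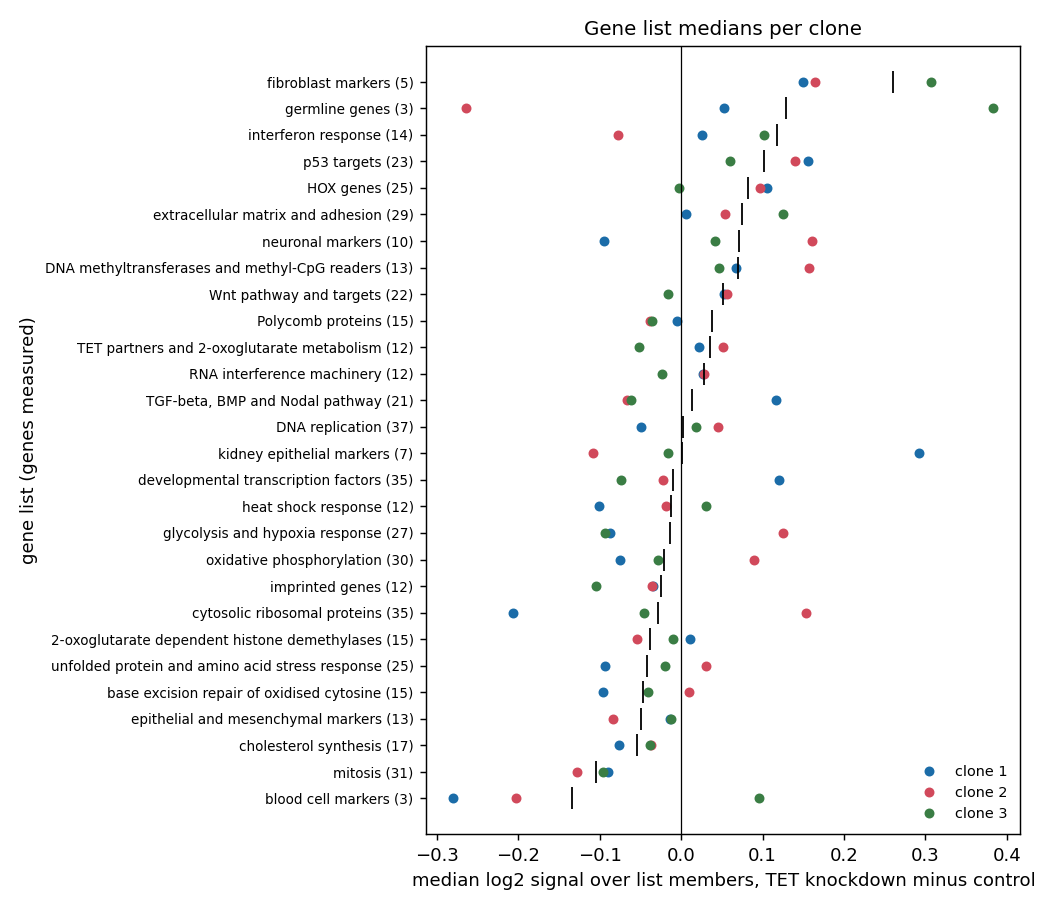
Median log2 signal in the knockdown minus control over the measured members of each gene list other than the TET genes, with points for the 3 clones and a tick for the median over the group difference; the number of measured genes stands in brackets. The mitosis list lies below 0 in all 3 clones (tick at -0.10) and the p53 list above 0 in all 3 (tick at 0.10), but several lists without a call also have all 3 clones on 1 side. The ribosomal list has clones on both sides of 0.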

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

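The fits that combine the replicate block with another choice, the random block and the loess correction were chosen after seeing the data; the other alternatives were planned. TET1, TET2 and TET3 stayed lower and past the threshold over the TET probe sets in all 25 alternatives, with log2 differences of -2.61 to -2.30, -1.22 to -0.90 and -1.30 to -1.07 and a largest adjusted p of 0.00998. The count of 4 changed probe sets was 3 with no filter on dim probe sets, 4 with the pseudocount and 6 with quantile normalization, but 14 with the upper 30% of probe sets, 1 without trend and robust steps, 25 at an adjusted p under 0.1, 1805 at an unadjusted p under 0.05 and 0 with the plain t-test and Benjamini-Hochberg adjustment (2004 at an unadjusted p under 0.05). Leaving out 1 array or 1 clone gave 0 to 121, the 121 without replicate 1 of both groups and 0 without replicate 2 or replicate 3. The replicate block gave 282, and with it the count was 70 with no filter, 368 with the upper 30%, 305 with the pseudocount, 231 with quantile normalization, 233 with the trend and no robust step, 0 with neither, 224 after loess, and 108, 684 and 63 without replicates 1, 2 and 3; the clone as a random replicate block gave 107, of which 106 were among the 282. Of the 282, 70, 258, 282, 221 and 220 were also called with no filter, the upper 30%, the pseudocount, quantile normalization and loess. With the block, 6 arrays leave few residual degrees of freedom, and most of the median total of 11.4 was borrowed across probe sets. The counts with the block therefore lean on the moderation. Leaving out a clone leaves fewer still. Why the count differs between the clones left out was not tested. Signal over background limits the dim probe sets, which the filter leaves out.

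For single genes, 74 results over 25 alternatives gave 1557 values with the direction and side of the threshold kept, 246 now past it, of which 223 came with a replicate block, 19 no longer past it (CCNB2 and the unnamed probe set) and 6 with a changed sign. Those 6 belong to ribosomal and blood genes that passed in none of them: over arrays and clones left out, RPS16 ranged from -0.21 to 0.05, RPLP1 from -0.17 to 0.044 and ITGAM from -0.25 to 0.06, and with the replicate block without replicate 1, RPLP1 was 0.018 and ITGAM 0.06. The cause was not tested.

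For the 29 lists, 866 values kept direction and side in 746, passed anew in 15, no longer passed in 6 and changed sign in 99. Camera does not use the empirical Bayes settings, so list values under those settings only repeat the values of the same fit. The number of lists called was 2, and 2 to 4 with arrays or clones left out (4 without replicate 2), 4 with the replicate block without replicate 2, 0 with an estimated correlation with or without the block, and 1 for fry with the block. With an estimated correlation the TET list (median -1.22) and the mitosis list (-0.10) lost their calls (adjusted p = 0.0607 for both, and 0.484 for both with the block), and with the block under fry their adjusted p was 0.0562 and 0.0642. Without the block, the correlations estimated for the TET and mitosis lists were -0.105 and -0.021, below the preset of 0.01. The p53 list passed with the replicate block (0.10). With the block it also passed with no filter (0.10), the pseudocount (0.10), quantile normalization (0.11) and loess (0.11), and without replicate 2 (0.10) or replicate 3 (0.12). Over arrays and clones left out without the block its median was 0.01 to 0.14. The replicate block alone changed no other list call under camera.

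Most sign changes were in small medians of lists that passed in neither setting, and the only list called after such a change was that of ribosomal proteins, whose median ran from -0.12 to 0.086 over arrays and clones left out (highest without knockdown replicate 1, adjusted p = 4.85e-06 at the preset correlation). With no filter, with or without the block, the medians were -0.27 for germline genes, 0.0076 for developmental factors, -0.023 for Wnt genes and -0.19 for kidney markers. With the upper 30%, with or without the block, they were -0.077 for interferon genes and -0.0021 for TGF-beta genes, and with the pseudocount -0.0011 for kidney markers. Quantile normalization, with or without the block, gave 0.012 for heat shock, -0.0043 for TGF-beta and -0.035 for kidney. Loess with the replicate block gave 0.013 for heat shock, 0.0032 for glycolysis, 0.0024 for oxidative phosphorylation, 0.0085 for ribosomal proteins, -0.0028 for TGF-beta and -0.037 for kidney. The mean of all probe sets gave -0.023 for Polycomb, 0.012 for developmental factors, 0.0020 for heat shock, 0.013 for oxidative phosphorylation and -0.0079 for TGF-beta.

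With the replicate block without replicate 1, medians were 0.046 for base excision repair, 0.0034 for imprinted genes, 0.024 for heat shock, 0.017 for glycolysis, 0.020 for oxidative phosphorylation, 0.053 for ribosomal proteins, -0.055 for TGF-beta, 0.020 for epithelial and mesenchymal markers, -0.10 for kidney and 0.064 for blood. Without replicate 2 they were -0.021 for Polycomb, 0.014 for developmental factors, -0.0070 for replication and 0.024 for epithelial and mesenchymal markers, and without replicate 3 they were 0.0047 for imprinted genes, -0.011 for replication, 0.021 for glycolysis and -0.0048 for fibroblast markers. Over arrays and clones left out without the block, medians ranged from -0.060 to 0.046 for base excision repair, -0.11 to 0.0024 for histone demethylases, -0.031 to 0.040 for Polycomb, -0.11 to 0.075 for imprinted, -0.15 to 0.28 for germline, -0.12 to 0.073 for developmental, -0.040 to 0.16 for interferon, -0.030 to 0.082 for RNA interference, -0.011 to 0.038 for replication, -0.14 to 0.030 for unfolded protein, -0.066 to 0.042 for heat shock, -0.080 to 0.064 for glycolysis, -0.047 to 0.020 for oxidative phosphorylation, -0.024 to 0.096 for Wnt, -0.13 to 0.085 for TGF-beta, -0.069 to 0.20 for matrix, -0.074 to 0.024 for epithelial and mesenchymal, -0.10 to 0.089 for kidney, -0.086 to 0.32 for fibroblast and -0.25 to 0.064 for blood cell genes. The cause of these sign changes was not tested.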

Other observations

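The tests of RNA integrity, array scaling, brightness and the share of CCNB2 in the mitosis list, and the choice of genes in the paragraphs on cell cycle genes and on further single genes, came only after the results they bear on had been seen.

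Among the 282 probe sets that passed with the clone as a replicate block, genes of the cell cycle went both ways; those given here were chosen after their values were seen. Among those lower, the G1 kinase CDK6 differed by -0.68 and -0.46 on the log2 scale at 2 passing probe sets (limma adjusted p with the replicate block 0.0021 and 0.0084), and its partner CCND2 by -0.59 (0.0028). CEP55, which acts in the last step of cell division, differed by -0.55 (0.0037). The checkpoint gene BUB3 had -0.57 and -0.56 at 2 passing probe sets, but -0.07 and -0.05 at 2 brighter ones. The proliferation marker MKI67 had -0.52 at its brightest probe set (0.0080) and -0.02 to -0.13 at the other 3. Others were higher: CCNE2, a cyclin of the G1 to S transition, by 0.37 (0.0447), the centriole genes CEP135 by 0.43 (0.0411) and CETN2 by 0.39 (0.0443), USP37, a deubiquitinase that acts at entry into S phase, by 0.48 (0.0274), and ANAPC16, a subunit of the anaphase-promoting complex, by 0.37 (0.0455) at 1 of its 4 tested probe sets and by -0.01 at its brightest. None of these passed without the clone in the fit, and no enrichment beyond the fixed lists was tested.

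Further single genes of that set, also picked after their values were seen, stand for no tested group. SPTSSA, a small subunit of serine palmitoyltransferase, which starts sphingolipid synthesis, was lower by 0.72 and 0.79 on the log2 scale at its probe sets (adjusted p with the replicate block 0.0021 and 0.0022), and SPTLC2, a catalytic subunit of the same enzyme, differed by -0.52 (0.0321). The receptor tyrosine kinase ERBB3 differed by -1.23 at its brightest probe set (0.0038) and by 0.12 at its dimmest. The chemokines CXCL8 and CXCL2 were 2.18-fold and 1.87-fold higher (0.0072 and 0.0467), both at probe sets of the type that can cross-hybridise, and the tetraspanin TSPAN2 was 2.48-fold higher at its brighter probe set (0.0028). Without the clone the same genes had adjusted p-values of 0.109 to 0.705.

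Probe sets that passed with the replicate block were more often lower than higher in the knockdown: 177 of 282, or 62.8% (95% Wilson interval 57.0 to 68.2%). The share was 72.3% after quantile normalization and 71.4% after removal of each array's smooth trend against brightness, so neither correction removed the excess. Both moved the median difference of all tested probe sets from 0.019 to 0.0037 and 0.0041, which works against rises (105 before, 64 after each). A higher share of falls therefore does not decide on scaling or brightness. Called falls were brighter than called rises (median log2 signal 11.8 against 10.9, and 9.67 over all tested). The intervals treat probe sets as independent, although some genes have several. Loss of RNA integrity stays open: the 3′ to 5′ ratio was higher in the knockdown in 1 of 3 clones for ACTB (mean paired difference -0.048, 95% interval -0.369 to 0.272) and in 2 of 3 for GAPDH (0.0044, -0.035 to 0.0437), and both intervals include 0. The excess is not a feature of all small differences: falls were 42.6% of probe sets at an unadjusted p under 0.05, and 49.1% of the calls without clone 2. The share was 81.5% without clone 1, 81.0% without clone 3 and 82.9% with no filter on dim probe sets, so it depends on the clones and the filter. Off-target silencing by the siRNAs may add falls and stays open, as siRNA and transcript sequences were not used here; a biological effect of TET loss stays open too.

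The lower mitosis list could rest on CCNB2 alone, but without it the median was -0.10 over 30 genes, 24 of them negative, and camera with the preset correlation gave p = 5.78e-06 (2.78e-05 with the replicate block, and unadjusted p = 0.0067 and 0.046 with an estimated correlation). This argues against a single-gene cause. Whether fewer cells were in mitosis or the genes were transcribed less was not measured.

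SESN1, SESN3, SELENOP and TP53INP1, all higher in the knockdown, are known targets of FOXO transcription factors, which led to the hypothesis of a broader FOXO response. It was tested on 21 other FOXO targets listed before their values were looked at. Their median difference was 0.032 on the log2 scale (95% bootstrap interval -0.109 to 0.0926), and 11 of 21 were positive. With the replicate block, camera in limma gave an unadjusted p of 0.876 for them. The interval, drawn over genes and not over clones, lies below the smallest of the 4 rises, 0.43. Those 4 genes were noticed because they rose, so this does not exclude a milder FOXO response. No shared rise of the other targets was found.

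For the splits of the arrays, the real grouping gave 4 probe sets without the clone and the highest of the other 9 groupings gave 0, so 1 of 10 splits reached that count. With the replicate block, the real grouping gave 282 and the highest of the other 3 splits that part every clone pair gave 0, so 1 of 4 did; those others mix knockdown and control arrays within each group. Both sets of splits are too few for a share under 0.05.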
